A study of Caenorhabditis elegans with 16 samples.

How the data were processed

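RNA was sequenced from first-stage (L1) larvae of Caenorhabditis elegans of 2 strains, the N2 wild type and cdk12-as, a strain whose CDK-12 kinase carries an analog-sensitive change that lets a bulky compound block it. Per the labels' protocols, bleached embryos hatched without food at 20 °C for at least 12 h and arrested as L1 larvae. The arrested culture was sampled or was divided for 4 h between starvation with DMSO, OP50 bacteria as food with DMSO, and food with the analog inhibitor 3MB-PP1 at 1 µM. Total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced in paired-end mode on an Illumina HiSeq, per the labels' protocols. Strain, condition and replicate number came from the labels, which gave 8 groups of 2 libraries, 16 in all. The labels call these separate replicates without naming separate cultures, so p-values measure the spread between these samples, which may be technical.

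Whole-number read counts for 24654 genes per library were analysed as the authors deposited them. Trimmomatic, HISAT2, featureCounts, DESeq2, deepTools 3.2 and genome build ce10 are named, without roles, per the submitters' processing notes. The counter, its strand setting for the gene counts and whether it counted reads or read pairs are not given in the sources used here. For that reason values of antisense genes, overlapping genes and near-identical family members (histones, nspe and cyp-25A genes, collagens and others) are uncertain. Lines of the deposited count table that name no gene were left out of library sizes and tests. Reads without a feature made up 23.65 to 57.06% of each column and ambiguous reads 0.83 to 10.7%, while the other special lines held 0. A second deposited table lists exon positions and exon lengths of 42048 genes on ce10, made by featureCounts 1.5.0-p2 with strand setting 2, per the file header. Its positions placed 24100 of the counted genes on one chromosome and strand with a span of at most 100000 bases. Gene biotypes and current names came from the Ensembl annotation of WBcel235, which was used for no coordinate, and 23892 counted genes had a biotype there. The 32 columns of spliced-leader (SL1 and SL2) counts in the second table carry codes that match no sample label and were not used. The 4 results and the operon class that were to rest on them are not reported. The class was planned on sums over all libraries, which need no match of codes to samples, but it was not built.

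Gene counts summed to 18588196 to 56644943 per library. One ribosomal RNA gene, rrn-2.1, took 34.79 to 50.7% of them in the replicate 1 libraries and 20.3 to 33.39% in the replicate 2 libraries, which left 13737620 to 36495804 counts for all other genes. The 2 libraries of a group differed by far more than sampling noise, with chi-square per degree of freedom of 55.1 to 468.0, and all were kept as separate libraries.

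Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups given (minimum count 10), which left 15845. One negative binomial model of 8 group means was fitted to all 16 libraries with TMM scaling, because 2 libraries per group give few degrees of freedom alone, and contrasts were tested with the quasi-likelihood F test. The fit had 8 residual degrees of freedom, a median of 4.2 prior degrees of freedom and a biological coefficient of variation of 17.3%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes are the absolute change divided by the square root of F. Levels are CPM computed with TMM-scaled library sizes. Whether the inhibitor or food acted differently in the strains was tested as an interaction contrast. All tests are two-sided.

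Gene lists, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined. Of 39 lists, 38 matched counted genes. The list of mitochondrial-genome mRNAs matched none, so scaling to those mRNAs was not run. The list of yolk and adult markers had 3 measured members, below the minimum of 5, and was not tested. The 37 other lists were tested in 5 contrasts with camera in limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01) and adjusted together over 185 tests. They were tested again with an estimated correlation, and with fry, which asks if a list moved one way on balance. Single members were also adjusted over the list alone. Named genes are the 10 largest rises and 10 largest falls (5 each way for feeding with inhibitor, further starvation and strain contrasts) among called genes with a mean of at least 5 CPM, a letter and number symbol and the same direction in both replicates. To these were added up to 4 members per list with the smallest adjusted p, and cdk-12, ccnk-1, cdk-9 and ama-1 in every contrast. Pairs of neighbouring genes, the genes around gro-1, and 3 genes called by DESeq2 alone were chosen after their values were seen.

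A class of closely spaced genes was defined after the effect of gene spacing had been seen in these data, in place of the spliced-leader class. A coding gene was called downstream when the adjacent coding gene lies upstream on the same strand and ends at most 500 bases away. A gene that heads such a run was called first. An interposed coding gene on the other strand breaks a run. Within each library the mean log2 CPM of downstream genes minus that of their first genes was computed, a quantity no library scaling changes, and the 2 treated cdk12-as libraries were compared with the other 6 fed libraries over all 28 splits in an exact permutation test. The test was run again over the 16 splits that keep one library of each replicate number, added after the result had been seen.

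The steps were tested on simulated counts for the inhibitor contrast in fed cdk12-as, with 200 changes assigned among 15845 genes drawn from the real means and library sizes. The filter then left 15252 genes, and the counts here cover the changed genes among those. The edgeR test recovered 0 of 48 genes changed 1.25-fold, 2 of 50 changed 1.5-fold, 23 of 49 changed 2-fold and 37 of 48 changed 4-fold. Among genes of at least 5 CPM it recovered 0 of 21, 2 of 26, 21 of 29 and 28 of 28. It called 3 of 15018 unchanged genes there and 0 of 15252 when nothing was changed in wild type. Camera called a list of 39 members shifted by 0.3. Of 200 unchanged lists, camera called 7 at the unadjusted level. Simulated genes varied independently and without a replicate effect. The count therefore says nothing of lists with correlated members, such as cytosolic ribosomal proteins (estimated correlation 0.64).

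Alternatives were DESeq2 1.42.0, size factors (RLE), total count scaling, no filter beyond 1 count, at least 50 counts in 2 libraries, the groups of a contrast alone, a replicate block and leaving out each library in turn. Total count without rrn-2.1 was added after the share of that gene had been seen. Because the protocol splits one arrested culture between conditions, replicate numbers pair libraries within a strain. Deviations of same-numbered libraries from their group means correlated at 0.21 to 0.54 across genes within a strain and at 0.14 to 0.44 between strains.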

Results

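Ribosomal-RNA-depleted RNA was sequenced from arrested first-stage (L1) larvae of 2 Caenorhabditis elegans strains, wild type (N2) and cdk12-as, before and after 4 h with or without food and with or without the analog inhibitor 3MB-PP1. The 8 groups of 2 libraries were larvae at the start of the 4 h, starved for 4 h, fed for 4 h and fed for 4 h with 1 µM inhibitor, in each strain. Gene read counts of replicates 1 and 2 in wild type were 39285385 and 27131149 at the start, 35619751 and 18588196 after starvation, 35141011 and 19646994 after food, and 56644943 and 38935635 after food with inhibitor. In cdk12-as they were 25872927 and 42118911, 33494796 and 22383445, 24187171 and 46670760, and 31781198 and 54789454 in the same order. Of 24654 genes, 15845 were tested. Along the first principal component (41.9% of the variance of log2 CPM over all libraries), the 4 fed wild-type libraries lay at 78.6 to 79.3 and the 8 unfed libraries of both strains at -56.1 to -26.6. Fed cdk12-as libraries lay between them, at 11.5 and 18.8 without inhibitor and 0.6 and 3.8 with it. Values after ± are SE for log2 fold changes and SD (n = 2) for CPM, and p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

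Transcripts of cdk-12, which encodes the kinase that phosphorylates the C-terminal domain of RNA polymerase II with cyclin K, passed the test in no contrast without a replicate block. Wild-type larvae had 38.6 ± 2.4 CPM at the start, 45.8 ± 2.1 after starvation, 47.7 ± 7.7 after food and 46.6 ± 8.6 after food with inhibitor. The cdk12-as larvae had 37.7 ± 3.0, 42.6 ± 7.6, 43.6 ± 2.4 and 33.8 ± 3.0 CPM. Its log2 fold change with the inhibitor in fed cdk12-as was -0.37 ± 0.15 (adjusted p = 0.169). Because the strain carries an altered protein and not a deletion, this level does not check the strain labels. Cyclin K (ccnk-1) and ama-1, the largest subunit of RNA polymerase II, rose only in cdk12-as larvae fed with inhibitor relative to starved ones, by 0.47 (adjusted p = 0.0035) and 0.59 (adjusted p = 0.0111) on the log2 scale. Neither passed the test in any other contrast, and cdk-9 passed in none. Both calls were lost under total count scaling, and that of ama-1 without cdk12-as starved replicate 1 (adjusted p = 0.13) or fed inhibitor replicate 2 (adjusted p = 0.113). With the replicate number as a block, cdk-12 passed the test with the inhibitor in fed cdk12-as (-0.37, adjusted p = 0.0111) and in that group against starved larvae (-0.33, adjusted p = 0.0102). The block also called ama-1 with the inhibitor (0.39, adjusted p = 0.00657) and in its difference between strains (0.47, adjusted p = 0.0261), ccnk-1 with food in cdk12-as (0.29, adjusted p = 0.0398) and cdk-9 between starved strains (-0.36, adjusted p = 0.00903).

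Feeding of wild-type larvae was compared with starvation over the same 4 h to find which transcripts respond when arrested larvae meet food. The saposin-like gene spp-17 (chromosome I, 1016413 to 1017134 of ce10) rose from 0.0915 ± 0.13 to 93.2 ± 1.4 CPM, a log2 fold change of 9.65 ± 0.59 (adjusted p = 7.89e-08). The intestinal acid phosphatase pho-11 (II, 9931804 to 9934305) rose from 21.9 ± 0.49 to 595 ± 21 CPM, and the cuticle collagen col-149 (V, 10291769 to 10292787) from 1.86 ± 0.19 to 79.5 ± 2.5 CPM. The long noncoding RNA tts-1 (X, 1504126 to 1504836) fell from 3920 ± 33 to 156 ± 31 CPM, by -4.65 ± 0.2. The linker histone hil-1 (V, 14949787 to 14952598) fell from 129 ± 7 to 7.36 ± 0.13 CPM, and lipl-3 (V, 521813 to 524214), a lysosomal lipase used in fasting. Other large rises were spp-23 (6.84), the protease nas-3 (5.87), dod-24 (5.56), pcp-2 (5.35), dct-17 (5.17), asm-3 (4.44) and ugt-22 (4.27). Other large falls were fbxa-163 (-6.42), chil-28 (-4.75), cyp-37B1 (-4.61), cyp-33B1 (-4), pho-9 (-3.91), sulp-5 (-3.67) and glc-1 (-3.66). In all, 3868 genes rose and 3414 fell, with medians of 0.88 and -1.07 among them, and 1622 rose and 1849 fell more than 2-fold. Total count scaling, in which the rRNA gene rrn-2.1 weighs heavily, moved the median of all genes by -0.37 and gave 1314 rises and 3701 falls. Total counts without rrn-2.1 moved it by -0.25 and gave 2661 rises and 4925 falls.

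Camera called 7 lists of protein synthesis, folding and turnover upward with food in wild type, and 1 of them with an estimated correlation. Mitochondrial ribosomal proteins rose in 63 of 66 cases and fell in 1 (median 1.31, for instance mrpl-12 from 14.9 ± 0.75 to 60.2 ± 0.065 CPM, camera adjusted p = 2.98e-23), and this list kept its call with an estimated correlation (adjusted p = 0.00731). Cytosolic ribosomal proteins rose in 71 of 78 cases and fell in 1, with 73 rises adjusted over the list alone (rps-15 1.05 ± 0.11, rla-0 1.11; adjusted p = 1.42e-12, and 0.652 with an estimated correlation). Ribosome biogenesis genes rose in 35 of 42 cases and fell in 4, among them nol-5 of the box C/D snoRNP (2.74 ± 0.12) and the RNA polymerase I subunit rpoa-2 (2.2 ± 0.11; adjusted p = 3.96e-12, and 0.266 with an estimated correlation). Translation factors rose in 36 of 41 cases, 37 adjusted over the list alone (eif-3.D 1.92 ± 0.08; adjusted p = 3.60e-13, and 0.176 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 28 of 32 (fars-1 1.81 ± 0.08; adjusted p = 3.62e-12, and 0.176 with an estimated correlation). Proteasome subunits rose in 32 of 33 (pas-5 1.54 ± 0.10; adjusted p = 1.11e-12, and 0.384 with an estimated correlation). None of the members of these 3 lists fell. Of 19 heat shock genes 9 rose and 3 fell, 10 and 4 adjusted over the list alone, and the mitochondrial chaperonin hsp-60 rose from 133 ± 11 to 1270 ± 20 CPM (list adjusted p = 0.049, and 0.652 with an estimated correlation). The heat shock call was lost without wild-type fed replicate 1 (adjusted p = 0.0582) or starved replicate 2 (adjusted p = 0.0699), and rps-15 and rla-0 lost their own calls under total count scaling.

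Camera called 8 other lists upward with food in wild type, none of them with an estimated correlation. Of 61 replication and cell cycle genes 46 rose and 1 fell, 47 and 2 adjusted over the list alone, with mcm-4 of the replicative helicase at 1.93 ± 0.08 and pcn-1 (PCNA) at 1.86 ± 0.10 (camera adjusted p = 3.62e-12, and 0.171 with an estimated correlation). Core histones, whose near-identical copies make single values uncertain, rose in 15 of 32 cases and fell in 2 (his-68 2.83; adjusted p = 0.00669, and 0.695 with an estimated correlation). The DNA damage response list had 23 rises and 3 falls among 51 (msh-2 1.05; adjusted p = 0.00401, and 0.607 with an estimated correlation). The list of RNA polymerase II CTD kinases and transcription genes had 24 and 4 among 44 (rpb-10 1.49; adjusted p = 0.00134, and 0.384 with an estimated correlation). Spliceosome genes rose in 26 of 57 cases and fell in 10, 28 and 11 adjusted over the list alone (lsm-6 1.56; adjusted p = 0.019, and 0.652 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 18 of 39, 19 adjusted over the list alone (adjusted p = 0.00043, and 0.757 with an estimated correlation). Vacuolar ATPase subunits rose in 16 of 20 with 1 fall (vha-6 1.66; adjusted p = 0.000583, and 0.652 with an estimated correlation). UDP-glucuronosyltransferases rose in 27 of 63 cases and fell in 11, 30 and 12 adjusted over the list alone (ugt-34 4.39, ugt-18 -1.75; adjusted p = 0.0196, and 0.652 with an estimated correlation). The medians of the damage response (0.27), spliceosome (0.31) and UDP-glucuronosyltransferase (0.36) lists became -0.10, -0.07 and -0.01 under total count scaling, which ended the calls of the first 2 lists. The UDP-glucuronosyltransferase call was lost without wild-type fed replicate 1 (adjusted p = 0.0563).

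Camera called 5 lists downward with food in wild type, none of them with an estimated correlation. Autophagy and lysosome genes fell in 23 of 37 cases and rose in 6, 7 adjusted over the list alone, and the Atg8 homologs lgg-1 and lgg-2 fell from 350 ± 5.6 to 113 ± 1.6 and from 86.2 ± 5.1 to 23.1 ± 1.5 CPM (camera adjusted p = 0.000286, and 0.384 with an estimated correlation). Of 26 genes activated by the FOXO factor DAF-16, 13 fell and 0 rose, with the metallothionein mtl-1 at -3.49 ± 0.19 (adjusted p = 0.00134, and 0.607 with an estimated correlation). Cytochrome P450 genes fell in 33 of 67 cases and rose in 6 (cyp-32B1 -2.94; adjusted p = 0.000141, and 0.316 with an estimated correlation). Neuropeptide genes fell in 25 of 82 and rose in 3 (nlp-28 -1.86; adjusted p = 0.0398, and 0.789 with an estimated correlation). Body wall muscle markers fell in 7 of 12 and rose in 1 (myo-3 -1.65; adjusted p = 0.0355, and 0.673 with an estimated correlation). Total count scaling ended the calls of the neuropeptide and muscle lists, as did leaving out wild-type fed replicate 1 (adjusted p = 0.0835 and 0.0729), and the neuropeptide call was also lost without wild-type starved replicate 2 (adjusted p = 0.0662).

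The other tested lists were not called with food in wild type, and all of them but sperm markers had members that moved. Insulin-like peptides had 6 rises and 7 falls among 30 (daf-28 2.16 ± 0.29, ins-24 -1.73; median 0.34, -0.02 under total count scaling). Genes of the glyoxylate cycle, gluconeogenesis and trehalose had 2 and 7 among 16 (icl-1 -2), fatty acid oxidation 14 and 13 among 35 and fatty acid synthesis and desaturation 12 and 10 among 28 (fat-2 -1.72). Cuticle collagens had 13 and 26 among 114 (camera adjusted p = 0.283), and moulting genes 8 and 6 among 21 (fbn-1 3.74 ± 0.41, nhr-23 1.32). Glutathione S-transferases had 12 and 18 among 47 (gst-26 3.69) and C-type lectins and lysozymes 61 and 36 among 185 (clec-81 3.88, clec-76 -3.30). Digestive proteases had 8 and 11 among 34, with a median of 0.16 while camera pointed down. Chemoreceptors had 41 and 88 among 537, 22 and 71 adjusted over the list alone. Intestine markers had 2 and 4 among 10, epidermis markers 5 and 0 among 8, pharynx markers 1 and 5 among 14, neuron markers 2 and 8 among 25, germline markers 6 and 4 among 29, oocyte and early embryo markers 2 and 5 among 26 and sperm markers 0 and 0 among 5. Under total count scaling the medians of the fatty acid oxidation (0.05), fatty acid synthesis (0.11), moulting (0.27), C-type lectin (0.06) and digestive protease (0.16) lists also turned negative.

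Feeding of cdk12-as larvae without inhibitor asked how the engineered strain itself responds to food. It changed many of the same genes by smaller amounts: spp-17 rose from 0.251 ± 0.042 to 50.6 ± 9.6 CPM, pho-11 from 37.9 ± 0.58 to 642 ± 150 CPM and hsp-60 from 133 ± 14 to 801 ± 2.7 CPM. The collagen col-149 rose from 1.4 ± 0.41 to 14.2 ± 0.88 CPM, tts-1 fell from 4080 ± 470 to 1050 ± 85 CPM and hil-1 from 126 ± 2.7 to 33.8 ± 1.6 CPM. Other large changes were spp-23 (6.47), pcp-2 (4.08), cpr-5 (4.01), folt-2 (3.25), dod-24 (3.21), cyp-33B1 (-3.63), pho-9 (-2.67), mltn-1 (-2.56), hacd-1 (-2.55) and clec-76 (-2.34). In all, 2479 genes rose and 1917 fell, of which 652 rose and 609 fell more than 2-fold. With total counts without rrn-2.1 the split was 1958 and 2543, and total counts with it called 1165 genes in all. A fit to these 4 libraries alone gave 2144 and 1259. The falls numbered 1192 or 1208 without cdk12-as fed replicate 1 or 2 and 1238 without starved replicate 2. Rises shared with wild type numbered 2333 and shared falls 1620, and 18 genes called in both strains went opposite ways. Across genes, which are not independent replicates, the food responses of the strains correlated at r = 0.712 (Spearman rho 0.724) with a slope of cdk12-as on wild type of 0.437.

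**Figure D1:**
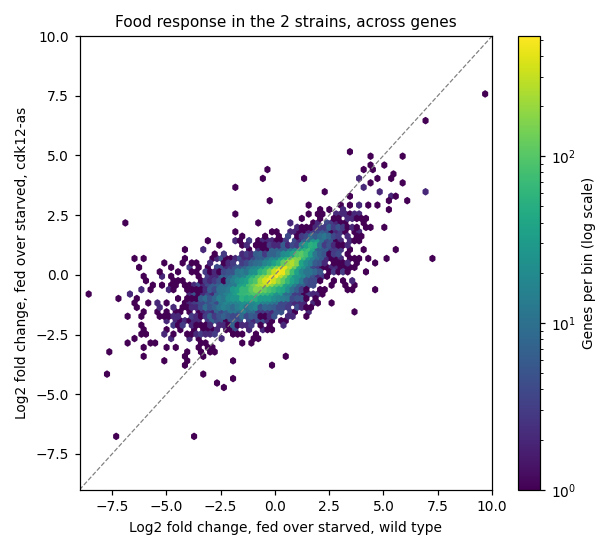
Food response of 15845 genes in cdk12-as (vertical axis) against wild type (horizontal axis), both as log2 fold change of fed over starved larvae, with colour for the number of genes per bin on a log scale and a dashed line of equal change. Most of the cloud is flatter than the dashed line, with a slope of 0.437 across genes.

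Camera called 21 lists with food in cdk12-as. Mitochondrial ribosomal proteins rose in 61 of 66 cases and fell in 1 (median 0.79, camera adjusted p = 4.24e-27, and 0.00731 with an estimated correlation). Cytosolic ribosomal proteins rose in 23 of 78 and fell in 1, 29 and 1 adjusted over the list alone (median 0.43, adjusted p = 8.91e-09, and 0.74 with an estimated correlation). Ribosome biogenesis genes had 33 rises and 4 falls, translation factors 29 and 0, aminoacyl-tRNA synthetases 27 and 0, proteasome subunits 31 and 0, replication and cell cycle genes 42 and 0, CTD kinase and transcription genes 25 and 1, and spliceosome genes 34 and 1 (largest adjusted p = 9.71e-09 among these 7, and 0.127 to 0.271 with an estimated correlation). Adjusted over the list alone those 7 lists had 35 and 4, 30 and 0, 28 and 0, 31 and 0, 46 and 0, 30 and 1, and 38 and 1. Autophagy and lysosome genes fell in 18 of 37 cases and rose in 2, 21 and 4 adjusted over the list alone (lgg-1 -0.52 ± 0.08; adjusted p = 0.00135, and 0.538 with an estimated correlation). The DAF-16 activated genes fell in 14 of 26 and rose in 1 (adjusted p = 0.00134, and 0.607 with an estimated correlation). Cytochrome P450 genes fell in 29 of 67 and rose in 7, 32 and 7 adjusted over the list alone (adjusted p = 0.000671, and 0.384 with an estimated correlation). Camera also called 9 other lists: oxidative phosphorylation, vacuolar ATPase, core histones, damage response and UDP-glucuronosyltransferases upward, and collagens, neuropeptides, body wall muscle and oocyte markers downward (adjusted p up to 0.049, and at least 0.602 with an estimated correlation). In that order they had 13, 5, 14, 14 and 23 rises with 0, 0, 1, 1 and 10 falls upward, and 19, 13, 3 and 2 falls with 5, 3, 0 and 0 rises downward. Adjusted over the list alone these were 13, 5, 15, 16 and 23 rises with 0, 0, 1, 2 and 13 falls, and 19, 12, 4 and 0 falls with 4, 2, 0 and 0 rises. In cdk12-as the median of the moulting list was -0.11 and of the C-type lectins -0.04 while camera pointed up, with neither called. The replicate block ended the collagen call (adjusted p = 0.0598) and added one for heat shock genes (adjusted p = 0.0339). Without cdk12-as fed replicate 1 the calls of collagens (adjusted p = 0.179), UDP-glucuronosyltransferases (0.055), muscle (0.137) and oocyte markers (0.26) were lost, and without fed replicate 2 those of vacuolar ATPase (0.0905) and neuropeptides (0.078). Without starved replicate 1 that of vacuolar ATPase was lost (0.0521), and without starved replicate 2 those of collagens (0.137), UDP-glucuronosyltransferases (0.0865), neuropeptides (0.118), muscle (0.251) and oocyte markers (0.109). Total count scaling ended the calls of vacuolar ATPase, neuropeptides and muscle markers and of lgg-1 itself.

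The food response itself differed between the strains for 1064 genes, 600 with a higher and 464 with a lower log2 fold change in cdk12-as. Some transcripts that food lowered in wild type fell less in cdk12-as. The gene fbxa-163 went from 15.5 ± 2.6 to 5.75 ± 1.6 CPM in cdk12-as. In wild type it went from 55.2 ± 2.4 to 0.665 ± 0.29 CPM, a difference in food response of 5.01 ± 0.47. The differences of tts-1 (2.69 ± 0.25, adjusted p = 0.000141), mtl-1 (2.27 ± 0.25), hil-1 (2.23 ± 0.19), cyp-37B1 (2.44), cdh-5 (3.14) and asp-12 (2.63) were of the same sign. Part of such a difference can lie in the starved level, which was lower in cdk12-as for fbxa-163 and cdh-5. For tts-1 and hil-1 the starved levels of the strains were close. Negative differences included dct-17 (-2.36 ± 0.4), dod-24 (-2.35 ± 0.2, adjusted p = 9.82e-05), cysl-2 (-2.1), gst-10 (-2.1), col-149 (-2.06 ± 0.37) and mth-1 (-1.98 ± 0.16), of which cysl-2 and col-149 lost their calls under total count scaling. The 3868 genes that rose in wild type had median changes of 0.88 there and 0.50 in cdk12-as, and the 3414 that fell had -1.07 and -0.52. Genes chosen by their call in cdk12-as gave the same order, with 1.00 against 0.70 for 2479 rises and -1.02 against -0.75 for 1917 falls. Total counts moved the median of all genes with food by -0.37 in wild type and by -0.06 in cdk12-as. That narrows the gap between the strains among rises and widens it among falls. With the replicate number as a block 2027 genes differed, 967 higher and 1060 lower. Total counts gave 168 higher and 8 lower, and total counts without rrn-2.1 904 and 154. No filter beyond 1 count gave 600 higher and 220 lower, and at least 50 counts in 2 libraries gave 915 and 297. Without wild-type starved replicate 1 or 2 the count was 528 or 494, and without wild-type fed replicate 1 or 2 it was 476 or 562. Without cdk12-as starved replicate 1 or 2 it was 626 or 598, and without cdk12-as fed replicate 1 or 2 it was 671 or 527. In each of these fits more genes were higher than lower, from 330 and 146 to 461 and 210.

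The inhibitor was compared with its absence in fed larvae of each strain to find which transcripts depend on CDK-12 activity. In cdk12-as, gst-24 (II, 13610410 to 13611224), a glutathione S-transferase, rose from 68.5 ± 0.2 to 375 ± 24 CPM, a log2 fold change of 2.45 ± 0.15 (adjusted p = 5.74e-07). The mRNA export factor aly-1 (IV, 9108931 to 9109651) rose from 45.2 ± 4.0 to 145 ± 5.2 CPM. The mitochondrial aspartyl-tRNA synthetase dars-2 (V, 12048727 to 12052052) fell from 11.4 ± 0.72 to 2.17 ± 0.00035 CPM (-2.39 ± 0.14), the aldehyde dehydrogenase alh-7 (II, 13487435 to 13491704) from 39.0 ± 0.67 to 8.66 ± 0.13 CPM, and crn-3 (II, 10587984 to 10592499), a component of the RNA exosome, from 64.8 ± 0.1 to 17.1 ± 1.2 CPM. Other large rises included dhs-23 (1.82), ugt-39 (1.64), gadr-6 (1.61), catp-3 (1.40), fbxc-52 (1.16) and cdr-2 (1.15). Other large falls were efl-2 (-2.26), snx-14 (-2.18), pinn-4 (-2.1), fre-1 (-2.07), the tRNA isopentenyltransferase gro-1 (-2.07), hint-1 (-2.03) and hpo-20 (-2.02). In all, 598 genes rose and 1326 fell, with 99 rises and 446 falls of more than 2-fold. Total counts moved the median of all genes by -0.21 and gave 44 rises and 783 falls. Without rrn-2.1 they gave 301 and 1577, and a fit to the 4 libraries of this contrast alone gave 190 and 915. The replicate block gave 1164 rises and 1643 falls. The rises numbered 267 or 322 without fed replicate 1 or 2 and 282 or 390 without fed inhibitor replicate 1 or 2, beside 1010 to 1095 falls.

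In fed wild type the inhibitor was followed by 0 called genes with edgeR, with 305 genes at an unadjusted p under 0.05, and DESeq2 called 3. These 3 were K08F8.5 (-2.48, DESeq2 adjusted p = 0.0107, edgeR 0.708), cnc-11 (-1.18, 0.0107 and 0.828) and cnc-6 (-0.80, 0.0135 and 0.708), all lower with inhibitor. Camera called 8 lists there, none with a member that passed the test over all genes. Their medians were -0.20 for pharynx markers, -0.14 for body wall muscle markers, -0.11 for DAF-16 activated genes, -0.06 for C-type lectins and lysozymes, -0.05 for vacuolar ATPase, 0.08 for replication genes, 0.08 for the damage response and 0.07 for the spliceosome (camera adjusted p = 0.000324 to 0.046, and 0.449 to 0.789 with an estimated correlation). Adjusted over the list alone 3 C-type lectin or lysozyme genes fell. Without wild-type fed inhibitor replicate 1 the vacuolar ATPase list was called in the other direction and the 7 others were not called (adjusted p = 0.154 to 0.954). Without wild-type fed replicate 1 the calls of vacuolar ATPase (0.0589), replication (0.194) and spliceosome (0.259) were lost, and without fed replicate 2 those of vacuolar ATPase (0.384), damage response (0.247), C-type lectins (0.0606), muscle (0.191) and pharynx (0.204). Total count scaling ended 5 of the 8 calls, and the replicate block added cytosolic ribosomal proteins (adjusted p = 0.0383) and glyoxylate cycle genes (adjusted p = 0.0165).

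The effect of the inhibitor differed between the strains for 1099 genes, 145 higher and 954 lower in cdk12-as than in wild type. The difference was 2.39 ± 0.2 for gst-24 (adjusted p = 2.4e-05), 1.64 for ugt-39, 1.52 ± 0.14 for aly-1, 1.49 for gadr-6 and 1.08 for sco-1, of which all but the first 2 lost their calls under total count scaling. It was -2.52 ± 0.19 for dars-2 (adjusted p = 1.24e-05), -2.36 ± 0.24 for gro-1, -2.29 for efl-2, -2.18 for fre-1, -2.17 ± 0.15 for alh-7, -2.12 for ceh-41 and -2.04 for phf-30. Total count scaling moved the median of all genes by -0.16 and gave 7 higher and 234 lower, and total counts without rrn-2.1 gave 84 and 1102. The number higher also depended on other settings: 337 with the replicate block, 79 with no filter beyond 1 count and 58 with the groups alone, beside 1201, 905 and 706 lower. It was 79 or 75 without wild-type fed replicate 1 or 2, 69 without cdk12-as fed replicate 1 and 88 without cdk12-as fed inhibitor replicate 1, beside 694 to 807 lower.

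Camera called 2 lists downward with the inhibitor in cdk12-as, the DNA damage response and mitochondrial ribosomal proteins, and neither with an estimated correlation. Of 51 damage response genes 23 fell and 6 rose, 23 and 8 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 2.39e-06, and 0.3 with an estimated correlation). Under total count scaling this median was -0.48. The FANCD2 homolog fcd-2 fell from 18.4 ± 0.63 to 7.6 ± 0.21 CPM, the mismatch repair gene msh-6 from 31.6 ± 0.96 to 12.7 ± 1.2 CPM, the Werner helicase homolog wrn-1 from 20.8 ± 1.1 to 7.80 ± 0.3 CPM and the nuclease gene xpf-1 from 20.8 ± 0.52 to 9.34 ± 0.84 CPM. The difference from wild type had 17 lower and 1 higher, 24 and 4 adjusted over the list alone (median -0.35, adjusted p = 1.36e-07, and 0.24 with an estimated correlation). Mitochondrial ribosomal proteins fell in 23 of 66 cases and rose in 3, 29 and 8 adjusted over the list alone (mrps-30 -1.70 ± 0.09, mrpl-21 -1.84; median -0.22, adjusted p = 5.06e-05, and 0.176 with an estimated correlation). Total count scaling brought the median of these proteins to -0.44. Their difference from wild type had 15 lower and 0 higher, 22 and 2 adjusted over the list alone (camera adjusted p = 2.96e-05, and 0.176 with an estimated correlation). Other lists had falls without a call for the list. Aminoacyl-tRNA synthetases had 9 falls and 2 rises, 10 and 3 adjusted over the list alone (dars-2, iars-2 -1.27, lars-2 -1.19; median 0.03 while camera pointed down). Oxidative phosphorylation had 7 falls and 0 rises (cox-11 -1.57, cox-15 -1.13; median 0.11 while camera pointed down). Replication and cell cycle genes had 7 falls and 2 rises, 7 and 3 adjusted over the list alone (sld-5 -1.50; median 0.07 while camera pointed down), and CTD kinase and transcription genes 7 falls and 9 rises, 7 and 12 adjusted over the list alone (the elongation factor spt-4 -1.50 ± 0.16). Translation factors had 5 falls and 2 rises, 5 and 5 adjusted over the list alone, and ribosome biogenesis genes 8 and 11, 9 and 17 adjusted over the list alone (nol-9 -1.33).

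Camera called 7 lists upward with the inhibitor in cdk12-as, and none kept its call with an estimated correlation. UDP-glucuronosyltransferases rose in 15 of 63 cases and fell in 4, 19 and 5 adjusted over the list alone (ugt-48 from 39.4 ± 2.8 to 75 ± 9.2 CPM, ugt-46 -1.15; camera adjusted p = 0.00103, and 0.602 with an estimated correlation). Cytochrome P450 genes rose in 6 of 67 and fell in 1 (cyp-33C8 0.86 ± 0.09; adjusted p = 0.0222, and 0.607 with an estimated correlation). Of the glutathione S-transferases 4 of 47 rose, 3 adjusted over the list alone (list adjusted p = 0.0544). Spliceosome genes rose in 20 of 57 and fell in 8, 23 and 10 adjusted over the list alone, with the Sm protein genes snr-4 and snr-7 at 0.62 ± 0.08 and 0.80 ± 0.10 and the methyltransferase prmt-5 at -1.09 (adjusted p = 0.00423, and 0.607 with an estimated correlation). Neuropeptides rose in 4 of 82, 0 adjusted over the list alone (adjusted p = 0.000765, and 0.652 with an estimated correlation). Insulin-like peptides rose in 1 of 30 (adjusted p = 0.049, and 0.621 with an estimated correlation). Cytosolic ribosomal proteins had 2 rises, 1 adjusted over the list alone (rpl-11.1 0.66 ± 0.11; median 0.20, which became -0.01 under total count scaling; adjusted p = 8.47e-05, and 0.809 with an estimated correlation). Collagens had no called member and a median of 0.21, which was 0 under total count scaling (adjusted p = 0.0208, and 0.621 with an estimated correlation). In the difference from wild type camera also called DAF-16 activated genes (median 0.41, adjusted p = 0.00213, and 0.607 with an estimated correlation), of which 0 of 26 passed the test. It also called C-type lectins and lysozymes upward (median 0.18, adjusted p = 0.0261, and 0.652 with an estimated correlation), although 2 of 185 members were higher and 4 lower, 0 and 0 adjusted over the list alone. In that contrast 1 cytosolic ribosomal protein was higher and 0 lower, 3 and 0 cytochrome P450 genes, 6 and 2 UDP-glucuronosyltransferases, and 0 and 0 collagens and neuropeptides. With the DNA damage response and mitochondrial ribosomal proteins called downward, no other list was called with the inhibitor in cdk12-as, but the replicate block added vacuolar ATPase (adjusted p = 0.0468) and DAF-16 activated genes (adjusted p = 0.0343). The insulin-like call was lost without any 1 of the 4 libraries, fed replicate 1 (0.126) or 2 (0.0598) and fed inhibitor replicate 1 (0.0676) or 2 (0.0846). The collagen call was lost without fed replicate 1 (0.188) or fed inhibitor replicate 2 (0.211), and the cytochrome P450 call without fed replicate 2 (0.203) or fed inhibitor replicate 1 (0.214). The difference for C-type lectins was lost without wild-type fed inhibitor replicate 1 (0.163), wild-type fed replicate 2 (0.117), cdk12-as fed replicate 1 (0.135) or cdk12-as fed inhibitor replicate 2 (0.136). Total count scaling ended the spliceosome call and those of ugt-48, cyp-33C8, snr-4, snr-7 and rpl-11.1.

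**Figure D2:**
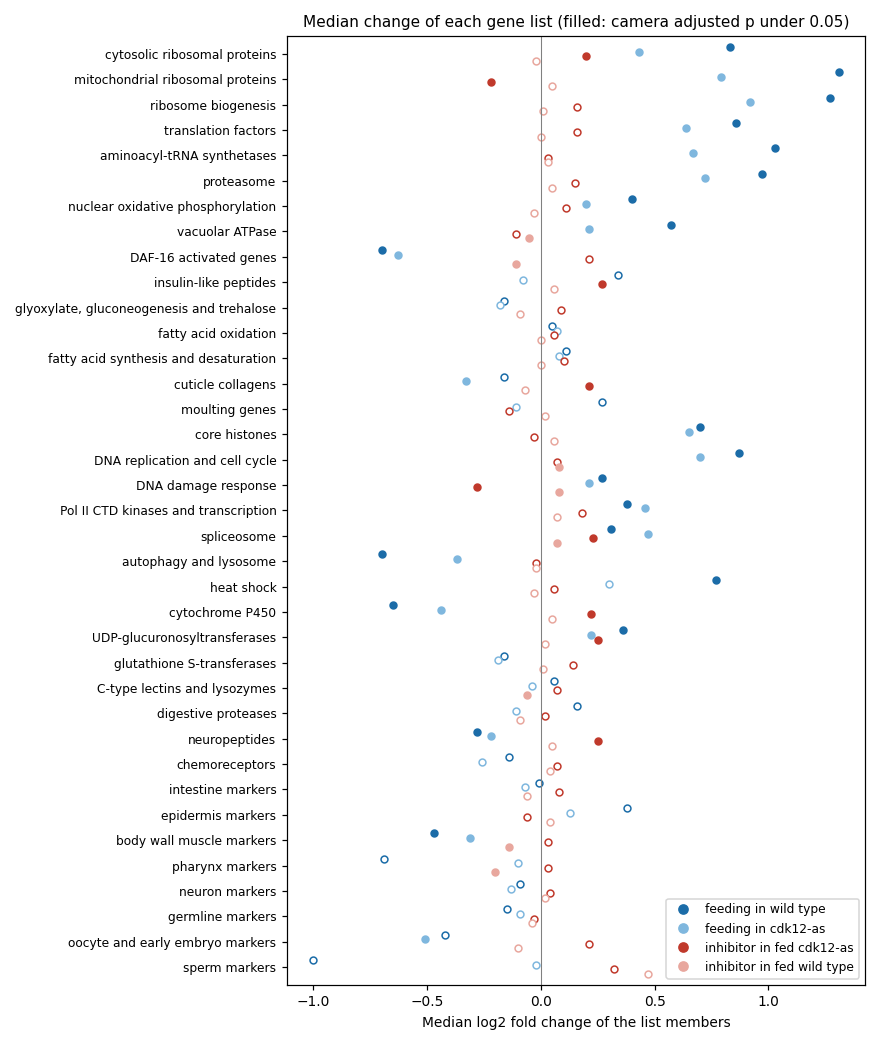
Median log2 fold change of 37 gene lists with food and with the inhibitor in each strain, with filled points where camera's adjusted p was under 0.05. Mitochondrial ribosomal proteins lie at 1.31 and 0.79 with food and at -0.22 with the inhibitor in cdk12-as, and several small positive medians of that contrast, such as that of cytosolic ribosomal proteins (0.20, then -0.01), turn negative under total count scaling, as do food medians in wild type such as that of the spliceosome (0.31, then -0.07).

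Many genes that fell with the inhibitor in cdk12-as lie just behind another gene on the same strand, an arrangement in which C. elegans genes are often transcribed together as operons. Of 1949 downstream genes, whose upstream neighbour on that strand ends within 500 bases, 568 fell (29.1%) and 54 rose, against 665 falls (6.2%) among 10749 coding genes outside such runs. Their median was -0.17 (camera adjusted p = 2.56e-13, and 0.0138 with an estimated correlation), and it was -0.37 under total count scaling and -0.26 without rrn-2.1 in the totals. The class was defined after the effect of spacing had been seen in these data. P-values for this class and its pairs are therefore no independent test. The 1383 genes that head these runs had 133 rises and 79 falls and a median of 0.14, which became -0.07 under total count scaling. Downstream genes were 43.3% of the 1312 fallen coding genes and 13.8% of all 14081 (odds ratio 6.3). The median was -0.12 for 1526 genes at position 2 of a run, -0.42 for 309 at position 3 and -0.66 for 114 at position 4 or later, where 24.3%, 43.7% and 54.4% fell. Positions were counted back only to the nearest untested gene, so genes behind one may lie later in their run. Only 1383 genes directly follow a tested head, fewer than the 1526 at position 2. The fall did not grow steadily with closeness: the 33 genes with gaps of up to 100 bases had a median of 0.03, and 63 genes that overlap their upstream neighbour had 0, with 11.1% falls. In wild type the downstream median was 0.06 and no downstream gene was called by edgeR (camera adjusted p = 0.0673); total count scaling brought it to 0, and it was 0.03 without wild-type fed inhibitor replicate 1 and 0.04 without wild-type fed replicate 2. The difference between the strains had 452 downstream genes lower and 13 higher (median -0.27, camera adjusted p = 4.7e-14, and 0.0138 with an estimated correlation). Its median was -0.43 under total count scaling.

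**Figure D3:**
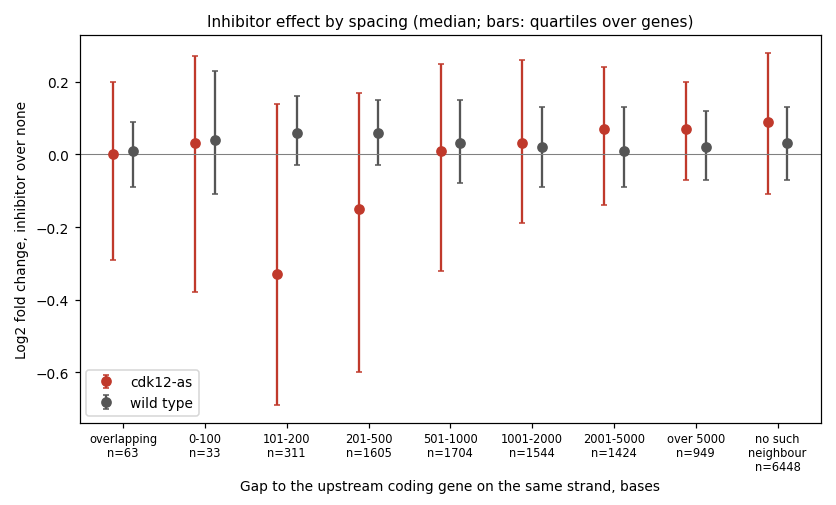
Log2 fold change with the inhibitor in fed larvae by the gap to the upstream coding gene on the same strand, as medians with bars for the quartiles over genes, for cdk12-as (red) and wild type (grey). In cdk12-as the median is -0.33 in the bin of gaps that ends at 200 bases, -0.15 in that ending at 500, 0.01 in that ending at 1000 and 0.07 above 5000, while it is 0.03 for the 33 genes with gaps of up to 100 bases and 0 for 63 overlapping genes.

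Over 1383 pairs of a downstream gene and the head of its run, the downstream gene had the lower log2 fold change in 70.6% with the inhibitor in cdk12-as and in 44.8% in wild type. The pairs named next were chosen after their values were seen. The ubiquinone biosynthesis gene clk-1 (III, 5277855 to 5279129) fell by 1.32 on the log2 scale (-1.32 ± 0.13) while toc-1, which ends 451 bases upstream, was at 0.09. The Mediator subunit gene mdt-17 (V, 20251938 to 20267198) had -1.67 ± 0.09 and its neighbour prmt-1 0.04, fnci-1 had -1.50 and hrpf-1 0.09, and fre-1 had -2.07 and the decapping scavenger dcs-1 -0.26 (adjusted p = 0.116). In other pairs both genes fell, as mrpl-21 (-1.84) and zhit-2 (-1.49) did. In the run that holds gro-1 (III, 5265097 to 5267091; -2.07 ± 0.18), the upstream genes hap-1 (-1.59 ± 0.14) and gop-3 (-1.19 ± 0.09) fell too, while ZC395.5, which starts 740 bases behind gro-1, was at 0.45 (adjusted p = 0.419). By the spacing rule hap-1 counts as the head of its run, since a gene on the other strand overlaps gop-3. Within each library the mean log2 CPM of downstream genes minus that of the heads of their runs, over the same pairs, was -1.24 ± 0.0086 (n = 2) in cdk12-as fed with inhibitor and -0.88 ± 0.05 in the other 6 fed libraries (exact two-sided permutation p = 0.036, the smallest that 28 splits allow). That test shuffles libraries across strains and replicate numbers, and replicate 2 was lower than replicate 1 in all 8 groups. Within replicate numbers the exact permutation p was 0.0625, the smallest that 16 splits allow, so the difference does not pass the test with this block. Within fed cdk12-as the value was -0.933 ± 0.015 without and -1.24 ± 0.0086 with inhibitor (n = 2 each), too few for an exact test of their own. The difference was -0.31 and -0.30 in replicates 1 and 2, beside 0.02 in both replicates of wild type. The lowest of the 14 libraries outside the treated group was at -0.944. Without either treated library the smallest p allowed is 0.14.

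**Figure D4:**
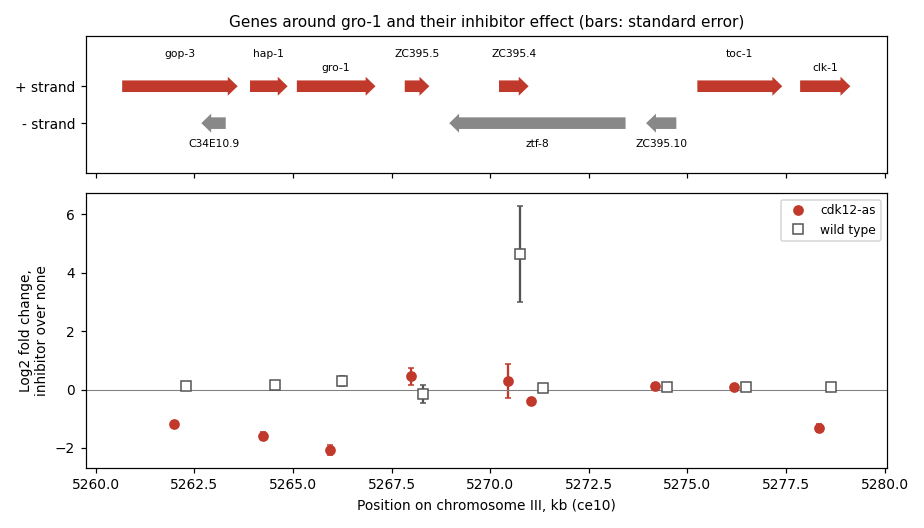
Genes around gro-1 on chromosome III (ce10) with strand, and the log2 fold change with inhibitor in fed cdk12-as (red) and wild type (open squares) with SE bars. In cdk12-as gop-3, hap-1 and gro-1 lie at -1.19, -1.59 and -2.07 and toc-1 at 0.09.

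**Figure D5:**
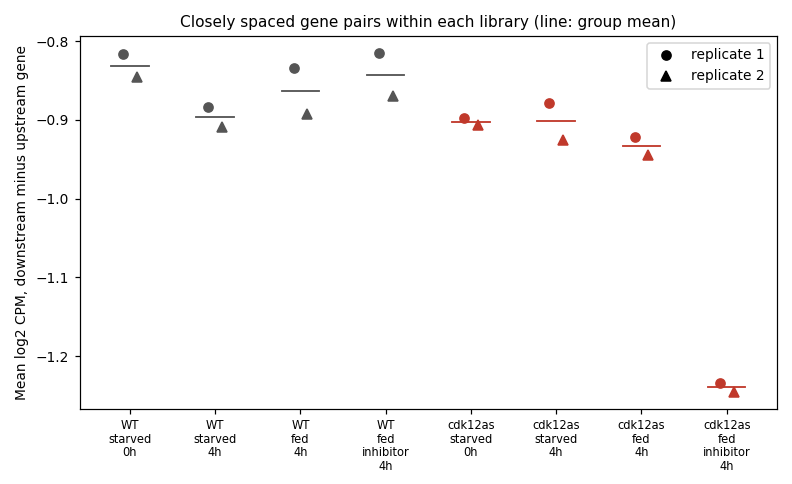
Mean log2 CPM of the downstream gene minus that of the upstream gene over 1383 closely spaced pairs in each of the 16 libraries, with a line at each group mean. The 2 libraries of cdk12-as fed with inhibitor lie at or below -1.234 and the other 14 at or above -0.944.

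Shorter genes had higher and longer genes lower log2 fold changes with the inhibitor in cdk12-as. The 20% of genes with the shortest span, up to 748 bases, had a median of 0.22 and 2.4% falls, and the 20% with the longest, from 4051 bases, had -0.06 and 17.8% falls. Across genes, which are not independent replicates, Spearman's rho of span and inhibitor effect was -0.29 in cdk12-as. For gene length, wild type, it was -0.063, with -0.186 among genes of at least 5 CPM and -0.033 and -0.014 in single replicates. Among genes of at least 5 CPM it was -0.358 in cdk12-as and -0.29 for the difference between the strains. Of the 3868 genes that food induced in wild type, 788 fell with the inhibitor in cdk12-as (20.4%, against 323.7 for independent lists) and 209 rose (against 146). Of the 3414 genes that food repressed 223 rose (6.53%, against 128.8) and 3.28% fell (against 285.7 genes). These differences were not tested. Across genes the wild-type food response and the inhibitor effect in cdk12-as, which share no library, correlated at r = -0.177. In wild type the same pair of contrasts shares the fed libraries, which by itself makes r negative, and r was -0.2505. In 100 simulations with no effect of food or inhibitor r was -0.499, a value that the sharing fixes in advance. A real food response changes r, so the simulated value is no measure for it. The covariance was -0.0382 beside -0.0666 in the simulations, and no reversal in wild type is read from these values.

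Larvae of cdk12-as fed with inhibitor were also compared with starved ones, to see how much of the food response remained with the kinase inhibited. The genes spp-17 (7.65 ± 0.54), spp-23 (6.49), cpr-5 (4.27), pho-11 (4.10) and pcp-2 (4.07) rose, and cyp-33B1 (-3.36), the lectin gene clec-76 (-3.26 ± 0.17), mltn-1 (-3.08), pho-9 (-2.64) and sulp-5 (-2.34) fell. In all, 2692 genes rose and 2713 fell. The 3868 genes that food raised in wild type had a median of 0.47 here, beside 0.50 in cdk12-as without inhibitor, and the 3414 that it lowered had -0.42 beside -0.52. Total counts moved the median of all genes by -0.26 and gave 726 rises and 2085 falls, and without rrn-2.1 they gave 1860 and 4063. For food without inhibitor total counts moved that median by only -0.06. The closeness of 0.47 and 0.50, and which of -0.42 and -0.52 is the larger fall, therefore depend on scaling. A fit to these 4 libraries alone gave 2328 rises and 1774 falls.

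Larvae starved for 4 h more were compared with those at the start of the split, to find what changed without food. The cytochrome P450 gene cyp-33B1 (V, 9041308 to 9043653) rose from 1.11 ± 0.16 to 11.9 ± 1.2 CPM in wild type and from 1.32 ± 0.18 to 31.2 ± 5.2 CPM in cdk12-as. The triglyceride synthesis gene dgat-2 rose from 9.27 ± 0.19 to 50.6 ± 1.9 CPM in wild type (2.45 ± 0.11), and dhp-1 rose by 2.27 ± 0.17 there and 1.97 ± 0.17 in cdk12-as. Other large rises were pho-9 (2.44) and cyp-36A1 (2.36) in wild type and ceh-23 (2.70), dpf-6 (2.03) and twk-25 (1.99) in cdk12-as. Large falls were ttr-50 (-4.07), dao-2 (-4.04) and the cuticle genes dpy-17 (-3.77 ± 0.84), sqt-3 (-3.65) and dpy-14 (-3.56) in wild type, and cut-3 (-2.85), dao-2 (-2.70), dpy-3 (-2.55) and col-113 (-2.15) in cdk12-as. No gene list was tested in these contrasts. Replicates of these differed widely, with dpy-17 at 7.14 ± 6.7 CPM after the 4 h. In wild type all 5 falls lost their calls without start replicate 1 (adjusted p = 0.0774 to 0.19) or starved replicate 2 (0.0915 to 0.206), and dao-2 also without starved replicate 1 (0.0524). In cdk12-as all 4 did without start replicate 1 (0.0574 to 0.264) or starved replicate 2 (0.0617 to 0.277), all but col-113 without starved replicate 1 (0.0692 to 0.102), and dpy-3 without start replicate 2 (0.0502). In wild type 482 genes rose and 487 fell, 949 and 895 with the replicate block, 94 and 284 with total counts and 352 and 594 with total counts without rrn-2.1. In cdk12-as 434 rose and 488 fell, 912 and 1035 with the block, 54 and 229 with total counts, 341 and 589 without rrn-2.1, and 111 and 86 in a fit to these 4 libraries alone. Single libraries weighed heavily: the wild-type count was 246 or 554 without start replicate 1 or 2 and 364 or 314 without starved replicate 1 or 2. The cdk12-as count was 116 without start replicate 1 and 322 or 179 without starved replicate 1 or 2. In these fits rises outnumbered falls, from 78 and 38 to 222 and 142, except without wild-type start replicate 2 (210 and 344). Falls also outnumbered rises without cdk12-as start replicate 2 (431 and 568).

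Unfed and fed larvae of the strains were compared in the same condition, to see how cdk12-as differs from wild type before any inhibitor. The predicted lipase gene lips-15 (II, 12605911 to 12606926) was higher in cdk12-as in all 3 conditions, at 33 ± 10 against 5.47 ± 0.16 CPM at the start, 44.9 ± 1.6 against 5.72 ± 0.71 after starvation and 23.4 ± 5.8 against 2.76 ± 0.078 after food. The lectin gene clec-82 was lower, at 5.91 ± 1.2 against 41.1 ± 3.2 CPM at the start (-2.79 ± 0.22, adjusted p = 8.36e-06), 8.42 ± 0.12 against 34.1 ± 1.1 after starvation and 8.46 ± 1.7 against 47.9 ± 12 after food. At the start nspe-7 (3.64 ± 0.44) and its near-identical family members nspe-1 (3.38) and nspe-6 (2.81), whose values are uncertain, were higher with spp-20 (3.25). Lower genes there were cyp-25A1 (-2.97), chil-28 (-2.93), cyp-25A2 (-2.11) and zim-1 (-1.89 ± 0.23), which acts in meiotic chromosome pairing. After starvation grd-5 (3.17 ± 0.19) and the antimicrobial peptide gene cnc-4 (2.66) were higher and cdh-5 (-2.43), lmd-5 (-2.17) and zim-1 (-2.17) lower. After food the neuropeptide-like gene nlp-34 was at 120 ± 0.64 CPM in cdk12-as and 14.6 ± 1.6 in wild type (3.05 ± 0.13, adjusted p = 9.89e-08), cht-1 was at 63.0 ± 25 and 6.11 ± 3.4 CPM, and asp-12 (3.05) was higher. The genes clec-170 (-3.31), col-149 (-2.49 ± 0.23), nas-3 (-2.11) and fbxa-136 (-2.1) were lower.

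These strain contrasts called 2029 genes higher and 1836 lower at the start, 1553 and 1312 after starvation and 2020 and 2559 after food. After food the 1949 downstream genes of closely spaced runs had 603 lower and 194 higher in cdk12-as without inhibitor, with a median of -0.22 (camera adjusted p = 0.00418, and 0.177 with an estimated correlation). These were 30.9% lower and 10% higher, against 15.2% and 14.6% of coding genes outside runs. Total counts moved the median of all genes in that contrast by 0.14, and by 0.18 without rrn-2.1, which shrinks this fall. The class had 308 lower and 185 higher at the start (median -0.08, camera adjusted p = 0.0941) and 239 and 163 after starvation (-0.1, 0.0729). Total counts gave 579 and 641 at the start, 564 and 486 after starvation and, with the direction turned, 1245 higher and 212 lower after food, where the scaling without rrn-2.1 gave 2728 and 1072. Filters turned splits too. After food it was 2013 higher and 1666 lower with no filter beyond 1 count, 2108 and 1763 with at least 50 counts in 2 libraries, and 1881 and 1422 with the groups alone. With at least 50 counts it was 1642 and 2126 at the start and 1261 and 1492 after starvation, and with no filter 1623 and 1793 at the start. Size factors (RLE) gave 1461 and 1480 after starvation. The direction with more genes thus depended on the setting in all 3 conditions. The count at the start was 2321 or 1830 without wild-type start replicate 1 or 2 and 1975 without cdk12-as start replicate 1. After starvation it was 1596 or 1368 without wild-type replicate 1 or 2 and 1579 or 1762 without cdk12-as replicate 1 or 2. After food it was 2720 or 2893 without wild-type replicate 1 or 2 and 2759 without cdk12-as replicate 2. Without cdk12-as fed replicate 1 it was 3216, with 1626 higher and 1590 lower.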

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

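The tests of expression, scaling, action of the compound and cotranscription for closely spaced genes, and of scaling and strain background for the food response, were chosen after the results had been seen; those of crowding, of the state before food and of rrn-2.1 were written before. The results here stand out because the effect of one treatment differed between the strains in a test of the difference itself.

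The inhibitor effect differed between cdk12-as and wild type for 1099 genes. Among gene lists the median difference of the inhibitor effect was 0.23 for cytosolic ribosomal proteins, -0.22 for mitochondrial ribosomal proteins, 0.41 for DAF-16 activated genes, 0.34 for cuticle collagens, -0.35 for the DNA damage response, 0.25 for cytochrome P450 genes, 0.32 for UDP-glucuronosyltransferases, 0.18 for C-type lectins and lysozymes and 0.2 for neuropeptides. Under total count scaling the first 2 medians became 0.07 and -0.36, and the others, in the same order, 0.24, 0.17, -0.51, 0.07, 0.15, 0.03 and 0.05. All 9 were called by camera with its preset correlation and none with an estimated one (adjusted p from 0.176 to 0.799). The collagen call was lost without cdk12-as fed replicate 1 (0.0693), wild-type fed replicate 2 (0.0742) or cdk12-as fed inhibitor replicate 2 (0.0717). The cytochrome P450 call was lost without cdk12-as fed inhibitor replicate 1 (0.155), wild-type fed inhibitor replicate 2 (0.197) or cdk12-as fed replicate 2 (0.162), and that of C-type lectins without 4 single libraries. The food response count was 476 to 671 without single libraries.

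Closely spaced downstream genes differed between the strains by a median of -0.27. With mean expression, exonic length and food response as terms, 94.7% of the excess fall of downstream genes in cdk12-as was kept, and the within-library gap of -1.234 or lower in both treated cdk12-as libraries, which no scaling changes, argues against library scaling. A median pair difference of 0.02 in wild type argues against an action of the compound without the engineered kinase. Without inhibitor, downstream genes were already lower in fed cdk12-as than in fed wild type (median -0.22). There 30.9% were lower, against 15.2% of coding genes outside runs, so the lower level of this class may not be tied to the inhibitor alone. A median of 0.11 for genes with a divergent neighbour as close argues against crowding by such neighbours. Convergent neighbours were not examined, and heads of runs were not removed from that set. The median of -0.66 at position 4 or later is what cotranscription from the promoter of the upstream gene predicts, so loss of transcription along such runs when CDK-12 is inhibited is a candidate explanation, found and tested on the same data. Whether transcription stopped early, trans-splicing failed or the RNAs were unstable stays open, since counts per gene hold no such information.

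Food changed 1064 genes by different amounts in the strains, and 1020 of them (95.9%) changed less in cdk12-as, without inhibitor. Of the genes called in cdk12-as, 71.7% or more changed less there with TMM scaling, among rises and falls alike. A scaling shift would move the shares apart, which argues against scaling as the whole cause. The shares were not computed with other scalings, and whether rises were smaller in cdk12-as at all depends on scaling. Total counts moved the median of all genes by -0.37 in wild type and by -0.06 in cdk12-as. They left 168 genes with a higher and 8 with a lower food response in cdk12-as. The strain difference at arrest between the genes food raised and lowered was 23.8% of the shortfall, which argues against a fed-like state at arrest as the whole cause. Food responses were measured from larvae starved for 4 h more, and that state was not used here. Genes were chosen by their call in wild type, which can enlarge the shortfall and lower the percentage. With library totals without rrn-2.1, 1058 genes differed and 754 of the 1064 were called in both fits, which argues against that gene as the whole cause, though the split moved from 600 higher and 464 lower to 904 and 154. The slope of 0.437 could come from the mutation itself, from the strain background or from slower food intake, and these cannot be told apart because each is tied to the strain.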

How the results depend on the processing

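The scaling without rrn-2.1, the spacing limits, each replicate number alone, the splits within replicate number and the fits of neighbouring pairs without single libraries were added after the data had been seen. Size factors (RLE), no filter beyond 1 count and at least 50 counts in 2 libraries kept every total of called genes within 1.5 times of the value reported, and DESeq2 did so except for the inhibitor in fed wild type (3 against 0). Total count scaling moved 10 counts: 1165 genes for feeding in cdk12-as, 827 for the inhibitor in fed cdk12-as, 241 for its difference between strains, 2811 for feeding with inhibitor, 176 for the difference in food response, 378 and 283 for further starvation in wild type and cdk12-as, and 1220, 1050 and 1457 for the strains at arrest, starved and fed. Without rrn-2.1 in the totals all counts stayed within 1.5 times, so the weight of that gene accounts for the drop. Fits to the groups of a contrast alone gave 1105 genes for the inhibitor in cdk12-as and 197 for further starvation there, with fewer libraries to estimate the spread. The replicate block gave 2027 genes for the difference in food response and 1844 and 1947 for further starvation in wild type and cdk12-as. The fit reported here ignores the pairing of replicate numbers. It leaves in the spread the deviations that same-numbered libraries of a strain share, which correlated at 0.21 to 0.54. Whether removing them gave the whole gain was not tested. For single genes and lists the block changed 13 calls, printed with the results they belong to or, for ins-36 with food in cdk12-as, lost (adjusted p = 0.0534). For the difference between neighbouring genes (-0.36) permutation within replicate numbers allowed 16 splits and gave an exact p of 0.0625. The block changed no other call. Of 603 results of named genes 557 were calls. Under total count scaling 367 kept the call and 190 lost it, 524 and 33 without rrn-2.1, 550 and 7 with DESeq2, 498 and 56 with the groups alone, and 2314 and 290 over the fits without single libraries. None reversed. Of the 46 that were no calls the block called 6, and each other setting 3 or fewer.

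Camera called 67 list results, and an estimated correlation left 2, which sets aside the preset of 0.01. Fry, which asks only if a list moved, left 147 of the 185 list results as they were, ended 26 calls and added 12. With the inhibitor in cdk12-as the fry adjusted p was 0.000107 for the DNA damage response and 6.18e-05 for mitochondrial ribosomal proteins. The wild-type median of closely spaced downstream genes with the inhibitor, 0.06, was no call (adjusted p = 0.0673), so only its unadjusted p (0.0274) was compared. The median was 0 and reversed under total count scaling. It was 0.06 with an estimated correlation, with fry and with a limit of 200 bases, and 0.05, 0.04 and 0.04 with limits of 1000, 2000 and 5000 bases, with an unadjusted p of 0.082 or more in each. The cause was not tested. In cdk12-as the median held its call in every setting run, at -0.37 to -0.01. The correlation for the reversal of the feeding response was -0.192 among genes of at least 5 CPM. That for gene length was -0.358 among those genes, -0.251 with exonic length, and -0.257 to -0.25 in single replicates. For gene length, wild type, it was -0.186 among genes of at least 5 CPM and -0.033 to -0.014 in single replicates.

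Without single libraries, where the lone library left in a group is assumed to vary like the other groups, the counts were 246 to 554 for further starvation in wild type and 116 to 999 in cdk12-as, 1830 to 3039 for the strains at arrest, 1368 to 1762 starved and 2720 to 3216 fed, and 476 to 671 for the difference in food response. The fewer libraries cost degrees of freedom. Counts stayed within 1.5 times for feeding in wild type (5864 to 6098) and cdk12-as (3124 to 3237), the inhibitor in cdk12-as (1289 to 1485), its difference between strains (769 to 1101) and feeding with inhibitor (4122 to 4318). The wild-type downstream median, which was no call, was 0.03 to 0.11, with 0.03 without wild-type fed inhibitor replicate 1 and 0.04 without wild-type fed replicate 2. The difference between neighbouring genes was -0.37 to -0.35, and without either treated library the 7 libraries left allow no exact permutation p under 0.14. One list reversed: for vacuolar ATPase, inhibitor in fed wild type, the adjusted p was 0.0289 in the other direction without wild-type fed inhibitor replicate 1, beside 0.046 in all libraries and 9.31e-06 to 0.384 without the other libraries of that contrast.

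Scaling to mitochondrial mRNAs, all alternatives of the 4 spliced-leader results and the operon class by spliced leader were not run. At these depths the simulated test recovered few changes of 1.5-fold or less, so such changes can go uncalled.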

Other observations

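The biotype and list-member counts, the matched lists other than the DNA damage response, the limits widened for correlation, the length values in single replicates and the reading of list members by gene spacing were chosen after results had been seen, and the tests of gene length and of the DNA damage response list were written before.

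Noncoding genes were also counted when wild-type larvae were fed, with no test of a difference from coding genes. Of 43 tested antisense RNAs 14 fell and 0 rose with edgeR, of 1192 short or unclassified noncoding RNAs 123 fell and 22 rose, of 93 lincRNAs 18 fell and 9 rose, of 244 snoRNAs 24 fell and 4 rose, of 44 snRNAs 2 fell and 2 rose, and of 133 pseudogenes 35 fell and 9 rose, beside 3121 falls and 3750 rises among 13744 coding genes. The coding split depends on scaling, with 4477 falls and 2582 rises for total counts without rrn-2.1 and 3362 and 1274 for total counts. The strand setting of the gene counts is not given, so antisense values are uncertain. In fed cdk12-as with inhibitor the median log2 fold change was 0.62 for 244 snoRNAs and 0.96 for 44 snRNAs, but only 2 of these genes passed the test, and both fell.

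Members that fell with the inhibitor in cdk12-as were counted by spacing in each list. Of 23 mitochondrial ribosomal protein genes that fell 16 were downstream, and the median was -0.52 for the 22 downstream members and -0.01 for the rest. Of the 8 ribosome biogenesis genes that fell 5 were downstream (medians -0.85 and 0.27; the list was not called), and of the 8 spliceosome genes that fell 6 were (-0.34 and 0.31; the list was called upward). Downstream genes were 4 of 9 fallen aminoacyl-tRNA synthetases, 4 of 7 oxidative phosphorylation genes, 3 of 7 each of the replication and the CTD kinase lists, 2 of 5 translation factors and 2 of 2 proteasome genes. They were 1 of 4 UDP-glucuronosyltransferases, 1 of 3 autophagy and lysosome genes, 0 of 5 C-type lectins and lysozymes, 0 of 3 moulting genes and 0 of 1 in the vacuolar ATPase, cytochrome P450 and intestine lists. Of 12 named large falls in the inhibitor contrasts, 7 were downstream within 500 bases (dars-2, alh-7, fre-1, gro-1, hint-1, crn-3 and phf-30) and 5 were not (efl-2, snx-14, pinn-4, hpo-20 and ceh-41).

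One hypothesis was that the fall of the DNA damage response list is what its members' spacing, span and expression give. Of its 23 fallen genes 10 were downstream, and the medians were -0.81 for downstream and -0.12 for other members. The list median of -0.28 lay at percentile 0.03 of 10000 random lists matched on those properties, whose medians centred on -0.05, with limits of -0.17 and 0.04. Random lists draw genes independently, while these members had an estimated correlation of 0.091, at which camera does not call the list (adjusted p = 0.3). Limits widened for that correlation were -0.3 and 0.19 and hold the list median. The widening is approximate, because the correlation is of members' residuals across libraries and not of their inhibitor effects. Spacing, span and expression as the whole account and a further dependence of these genes on CDK-12 thus cannot be told apart. Spliceosome genes at 0.23 lay beyond their matched limits but inside the widened ones (-0.1 and 0.27), and UDP-glucuronosyltransferases at 0.25 lay at the edge of theirs (-0.19 and 0.25). Mitochondrial ribosomal proteins at -0.22 lay outside both, with widened limits of -0.07 and 0.25, and cytosolic ribosomal proteins at 0.2 inside both.

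A further hypothesis was that long genes need CDK-12 more than short ones, since span and inhibitor effect were inversely related across genes in cdk12-as. The relation stayed at -0.299 among coding genes outside closely spaced runs, which argues against the downstream genes alone as its cause. Replicate libraries of one group differed with span by at most 0.084 (absolute Spearman rho), and by at most 0.142 among genes of at least 5 CPM, which argues against a length bias that varies between libraries as the whole cause. The partial rho given mean expression was -0.272, which argues against expression level. Against the hypothesis, wild type had a rho of -0.186 among genes of at least 5 CPM (-0.162 and -0.05 in single replicates), beside -0.358 in cdk12-as, so part of the relation may arise without the engineered kinase. The difference between the strains had -0.29 for those genes, with -0.251 and -0.271 in single replicates. A dependence of long transcripts on the kinase may contribute to that difference, and differences in RNA stability between long and short genes were not tested.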
